A study of Mus musculus with 12 samples.

How the data were processed

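RNA from the cerebellum of Ts1Cje and euploid mice was measured on 12 Affymetrix arrays, each carrying the same 12488 probe sets. Ts1Cje mice carry an extra copy of the distal part of chromosome 16 and serve as a model of Down syndrome. Per the labels' protocols, total RNA was extracted from frozen individual cerebella with a column kit, treated with DNase and checked for quality on a Bioanalyzer. RNA of several cerebella was then pooled, and an aliquot of each pool was made into biotinylated cRNA by the manufacturer's procedures. The 6 pools cover both genotypes at P0, P15 and P30 (postnatal days 0, 15 and 30). Each pool held 3 cerebella, except the euploid P30 pool with 2, and was hybridised to 2 arrays.

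The deposited values are linear signal intensities from MAS5, per the submitters' processing notes, in which the authors combined the probes of a probe set into 1 intensity. The MAS5 version and its settings are not given in the sources used here. From the values, all 12 arrays had been scaled to a common level: the mean of each array after trimming 2% of probe sets at each end lay between 100.05 and 100.06. No further scaling was applied. Signal over background sets the precision of an array value, and detection calls were not analysed here. The median signal per array was 30.4 to 36.2, so many probe sets lay close to background.

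Values were transformed to log2(signal + 4.6), where 4.6 is the 20th percentile of all deposited values. All fold changes are therefore on the log2(value + pseudocount) scale, which understates the change of dim probe sets. The 66 control probe sets were left out, as were probe sets with a mean signal under 20.1, the 40th percentile of the means, which left 7453 probe sets. Gene symbols came from the platform annotation, in which 10855 probe sets have 1 symbol, 396 have several and 1237 have none. Of those with 1 symbol, 10839 matched a RefSeq gene table (GRCm38.p6), used for names and gene order, and 0 symbols changed. A gene was represented by its probe set with the highest mean signal, which gave 5670 genes. A further 708 tested probe sets had no single symbol and were tested but not named.

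The log2 values of both hybridisations of a pool were averaged, so the pool was the replicate and each genotype and stage had 1 pool. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend over mean signal), and all tests were two-sided. Figures were drawn with matplotlib 3.10.9 in python 3.11.15. The additive model held genotype and stage, with 2 residual degrees of freedom and a fitted prior of 6.39. It gave the difference between genotypes over the 3 stages and the differences between stages over both genotypes. Another model added the product of genotype and postnatal day, with 1 residual degree of freedom and a fitted prior of 9.51. Adjusted p-values are by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. Standard errors are those of limma. The p-values measure the spread between these pools, and the number of arrays limits the precision. This spread mixes technical variation, that of a few animals and, in the additive model, any true change of the genotype difference with stage. An exact permutation of pools within stage cannot give a p under 0.25, and one of 3 pools against 3 cannot go under 0.1. Within a single stage no test among samples exists, and only values are given.

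Gene groups were 24 lists fixed before the data were examined, as were the model, the filter, the pseudocount and the naming rule. They were the trisomic segment of chromosome 16, the neighbouring segment of chromosome 16 present in 2 copies, a chromosome 12 segment near the translocation, Purkinje cells, mature granule cells, granule cell progenitors and Sonic hedgehog signalling, cell division, immature neurons, myelin and oligodendrocytes, astrocytes and Bergmann glia, GABA interneurons, synapse, ionotropic receptors, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, interferon response, stress and immediate early genes, microglia, endothelium, blood, choroid plexus and meninges, brainstem and hindbrain, and sex-linked genes. The 21 lists with 5 or more measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over lists within a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it. Within a stage, the median of a list was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins, as a description of the pools. A list of markers of brain regions next to the cerebellum was written later, before its own values were looked at.

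Genes are named by a fixed rule. For the stage comparisons it takes the 10 largest called rises and falls with the same direction in both genotypes. For the genotype comparison, with no call, it takes the 5 higher and 5 lower genes with the smallest p and the same direction in all 3 stages. In each list it takes up to 4 called members with the smallest adjusted p, or the brightest 2 members where none was called. On chromosome 16 it adds a fixed set of well-known genes and every trisomic gene past 0.05 when adjusted over the list alone. Within a stage it takes the 5 highest and 5 lowest differences with no overlap between the hybridisations of both pools among probe sets with a mean signal over 95.8. For the change of the genotype difference with day it takes the 5 up and 5 down with the smallest p. Other names were chosen after their values were seen, which is said where they appear.

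The fits were tested on simulated data with 20 repeats of 7453 probe sets, of which 200 were changed, 100 at each fold size. With variances drawn from the fitted prior, the genotype comparison recovered 14.7% of 1.5-fold and 73.5% of 2-fold changes, and 5.3% of calls were false. P15 against P0 recovered 62.4% of 2-fold and 98.8% of 4-fold changes, with 4.2% false. The day model recovered 4% of 2-fold and 32.5% of 4-fold changes, with 22% false calls. That share fell to 5.8% when the true prior was supplied, so a single residual degree of freedom leaves the prior poorly estimated. With each probe set's own moderated variance, 54% and 95.4% were recovered for genotype, 88.2% and 100% for P15 against P0, and 21.5% and 87% for day, with 7.2%, 6.9% and 14.6% of calls false. In simulated sets over 5670 genes, a list of 23 genes shifted 1.5-fold was called in 20 of 20 repeats at the preset correlation, 0 of 20 with an estimated correlation and 11 of 20 by fry. Without a shift, none of these tools called it in any repeat (0 of 20 each). Over the 20 repeats, other lists, none of them shifted, were called 2 times by fry without the shift, and 5 times by fry and 1 time at the preset correlation with it. Simulated genes varied independently of each other, so the simulation cannot judge the set tests where genes move together.

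The alternatives tried were quantile normalization, centring each array on its median, pseudocounts at the 5th and 40th percentile, no signal filter or one at the 60th percentile, eBayes without a trend, only probe sets without a design suffix, 1 probe set per gene, all 12 arrays with the hybridisation number as a block and the pool as a random block, either hybridisation alone, each pool and each stage left out, only the pools of the stages compared, other fold limits within a stage, and the other set tests. All were set down before the data were examined.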

Results

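Ts1Cje is a mouse line that carries an extra copy of the part of chromosome 16 corresponding to much of human chromosome 21, and euploid mice are its controls. The title and labels of the series set both genotypes side by side in the cerebellum at P0, P15 and P30, a period in which granule neurons are born and mature, Purkinje cells grow and myelin forms. The 12 arrays measured 6 RNA pools, 1 per genotype and stage, each on 2 arrays. Median signal per array ranged from 30.4 to 36.2. The ratio of 3' to 5' signal, a sign of RNA integrity, was 0.841 to 1.07 for the GAPDH controls and 1.13 to 1.67 for the actin controls. The 2 highest actin values belonged to the Ts1Cje P30 pool. Across 7453 probe sets, arrays of the same pool had a median Pearson r of 0.972 (6 pairs), arrays of the same stage but the other genotype 0.967 (12 pairs), and arrays of different stages 0.864 (48 pairs). The first principal component of the pools held 75.3% of the variance and ordered them by stage. Differences between genotypes were thus close in size to those between hybridisations of a pool, and differences between stages were far larger.

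The first question was whether the genes of the trisomic segment carried a dosage signal, which also checks the genotype labels. Nearly all measured genes of the segment were higher in Ts1Cje cerebellum at each stage, by a little less than the 1.5-fold that an added copy would give. They included Son, a splicing cofactor of nuclear speckles, Atp5o, a subunit of the mitochondrial ATP synthase, Ttc3, a ubiquitin ligase, Hmgn1, a nucleosome-binding protein, Itsn1, an endocytic scaffold, and Rcan1, an inhibitor of calcineurin. Of 68 genes in the list, 36 had a probe set and 23 passed the signal filter. The list median was 0.49 on the log2 scale, or 1.4-fold, with a mean of 0.46 and an SD over genes of 0.19. It was 0.48 at P0, 0.43 at P15 and 0.48 at P30, and no random list of matched signal reached these values at any stage (percentile 100 of 10000 lists each). All 23 genes had a positive difference over the 3 stages, and 20 of them kept 1 direction in all 3 stages (87%), where chance gives 25% for either direction; these 20 were higher.

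Camera called the trisomic list at the preset correlation (adjusted p = 1.77e-32), fry called it too (adjusted p = 0.00775), and the call was lost with an estimated correlation (adjusted p = 0.115 with an estimated correlation). Single genes reached no call over all 7453 probe sets, while 16 of the 23 passed when adjusted over the list alone, all of them higher. Son was higher by 0.75 ± 0.12 (log2 difference ± SE, n = 3 stages, limma adjusted p = 0.00594 over the list alone), with 0.91 at P0, 0.52 at P15 and 0.81 at P30. A second, dimmer probe set of Son gave 0.26. Setd4, a SET-domain protein, had the largest difference at 0.91 ± 0.24, and rested on a dim signal of 26.4. Differences between 0.5 and 0.62 were found for Cbr1, a carbonyl reductase (0.61 ± 0.13), Ifnar1, a chain of the type I interferon receptor (0.59 ± 0.16), Tmem50b (0.58 ± 0.11), and Psmg1, a proteasome assembly chaperone (0.58 ± 0.14). They were also found for C2cd2 (0.57 ± 0.16), Atp5o (0.56 ± 0.11), Vps26c (0.53 ± 0.13), Rcan1 (0.51 ± 0.15) and Paxbp1 (0.50 ± 0.14). Ttc3 and Hmgn1, both bright, gave 0.49 ± 0.10 and 0.48 ± 0.10, and Itsn1 gave 0.46 ± 0.12. Gart, an enzyme of purine synthesis, had 0.45 ± 0.14, and Ifngr2, a chain of the interferon gamma receptor, 0.43 ± 0.16. The remaining 7 members did not pass over the list alone. Among them were the kinase Dyrk1a at 0.26 ± 0.14, with 0.47 in a further probe set, and the transcription factor Ets2 at 0.23 ± 0.14, and Chaf1b had the lowest value, 0.087 ± 0.26.

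**Figure D1:**
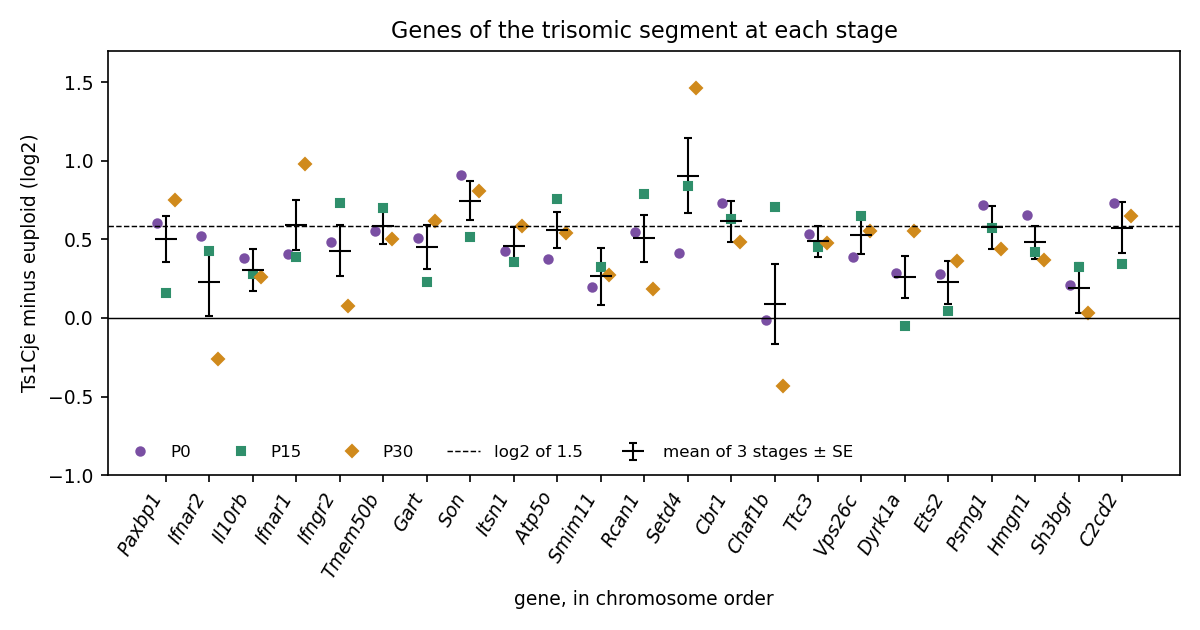
Difference between Ts1Cje and euploid pools (log2, vertical axis) for the 23 measured genes of the trisomic segment in chromosome order. Symbols are the 3 stages, black bars the mean ± SE, and the dashed line marks log2 of 1.5; all 23 means lie above 0, from 0.087 for Chaf1b to 0.91 for Setd4.

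Genes of chromosome 16 outside the segment showed no such shift. The list of genes present in 2 copies, which adjoins the segment, had a median of 0.021 over 11 genes (adjusted p = 0.948), and App, the amyloid precursor gene, had a difference of 0.057 ± 0.10. Among 171 measured genes of the chromosome, the 147 on the proximal side of Sod1 had a median of 0.015. Sod1 lies at the edge of the segment, where its extra copy is known not to give active enzyme, and was kept out of the list. Its difference was 0.44 ± 0.12, positive at each stage (0.63, 0.33 and 0.35) (adjusted p = 1 over all probe sets). No probe set carried the name of Olig1, Olig2 or Synj1, and Pcp4 and Kcnj6 lay below the signal filter. In the chromosome 12 list, 1 gene (Sp4) had probe sets and 0 passed the filter.

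**Figure D2:**
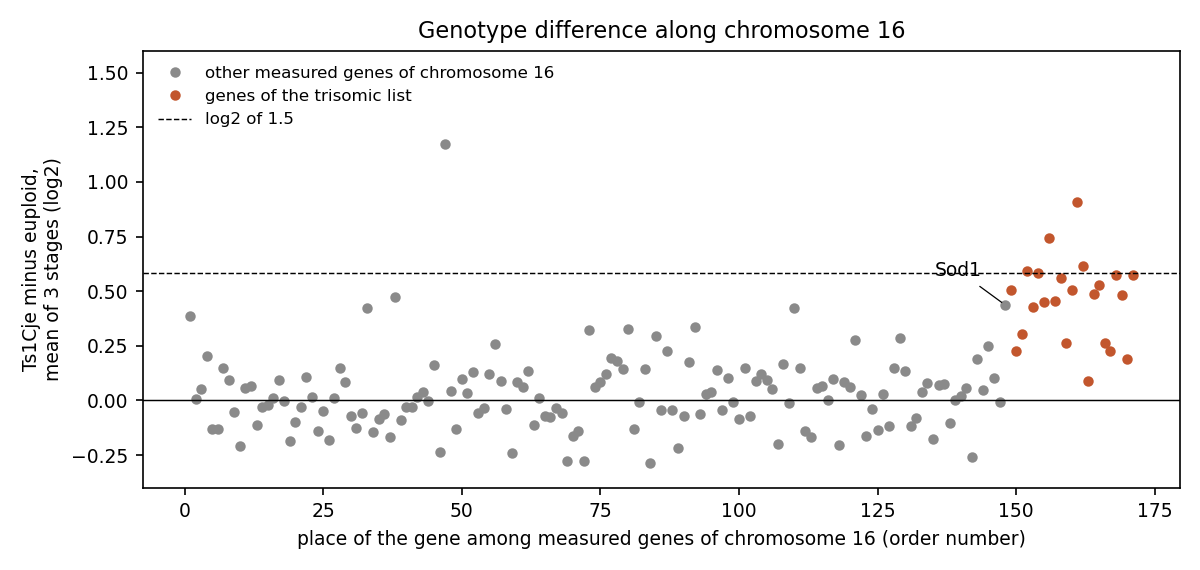
Difference between Ts1Cje and euploid pools (log2, mean of 3 stages, vertical axis) for 171 measured genes of chromosome 16 in gene order (horizontal axis). Genes of the trisomic list (red) fill the distal end, Sod1 stands at their edge, and the 147 genes before it have a median of 0.015; the dashed line marks log2 of 1.5.

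The next question was what else differed between the genotypes. Among the 5 lower genes with the smallest p were 3 erythroid ones: the globins Hbb-b2 and Hba-a1 and Alas2, the first enzyme of heme synthesis in red cells, had negative differences at each stage. Eomes, a transcription factor of unipolar brush cells and other glutamatergic lineages, P2rx6, a purinergic receptor subunit, Vwf, the endothelial clotting protein von Willebrand factor, and Cdca7l had positive differences at each stage. None of these passed correction. Limma called 0 of 7453 probe sets, 217 had an unadjusted p under 0.05 (2.91%) where chance gives 373, and 266 had one without the trend in eBayes. The error of this fit also holds any genotype difference that changes with stage, so these counts do not exclude such differences.

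Hbb-b2 had the smallest p, with -1.15 ± 0.15 (limma adjusted p = 0.321) and stage values of -0.68, -1.40 and -1.38. Hba-a1 stood at -0.83 ± 0.16 and Alas2 at -0.997 ± 0.21 (adjusted p = 0.61 and 0.753), and all hybridisations of the Ts1Cje pools lay below all those of the euploid pool of their stage for these 3 genes. The remaining lower genes were Sprr1b at -0.49 ± 0.12 and Astn1, a neuronal protein of glial-guided migration, at -1.10 ± 0.27. Eomes reached 1.13 ± 0.16 (adjusted p = 0.321), with 0.60 in another probe set. P2rx6, on chromosome 16 outside the segment, reached 1.18 ± 0.19, Vwf 0.80 ± 0.14 and Cdca7l 0.93 ± 0.18. Leaving out the euploid P30 pool or the Ts1Cje P30 pool gave 6 calls, all lower, which held Hbb-b2, Hba-a1, Alas2 and Astn1, and leaving out either P0 pool gave 1, Hbb-b2. With stage in the model, leaving out either pool of a stage takes that stage out of the genotype comparison. Both ways are thus the same check, with fewer residual degrees of freedom than the 2 of the full fit.

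**Figure D3:**
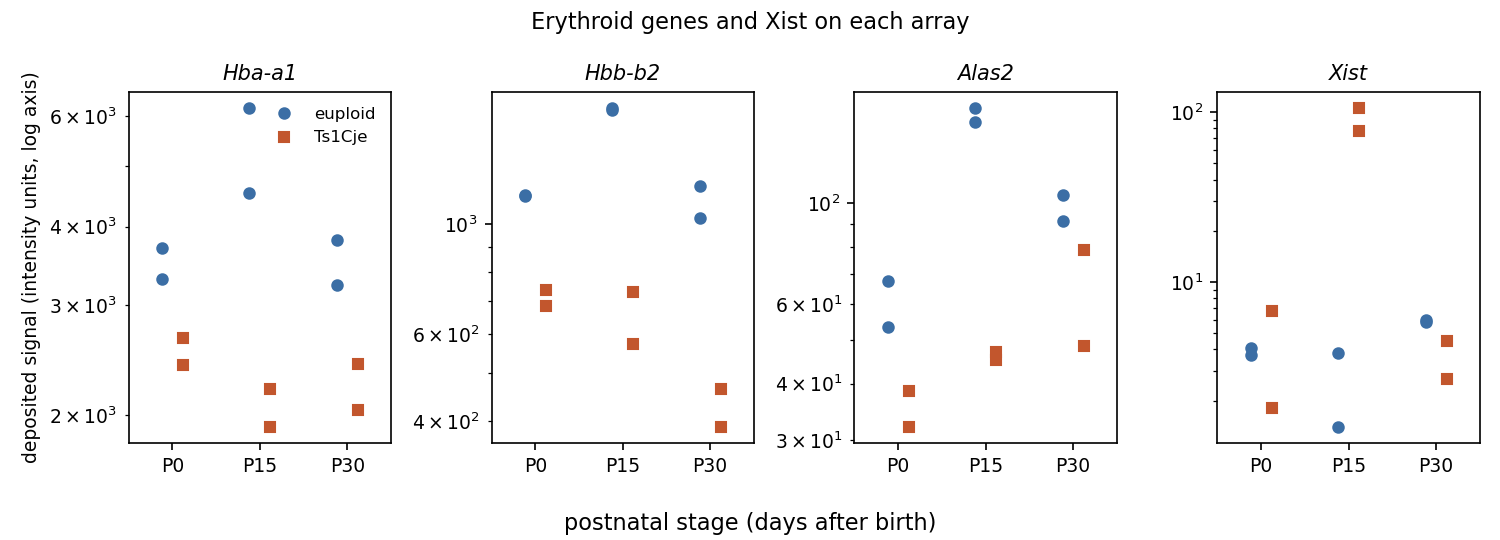
Deposited signal (intensity units, log axis) of Hba-a1, Hbb-b2, Alas2 and Xist on each of the 12 arrays, by stage; blue circles are euploid and red squares Ts1Cje, 2 hybridisations per pool. The 3 erythroid genes lie lower on the Ts1Cje arrays of each stage, and Xist stands at 105.6 and 77.6 in the Ts1Cje P15 pool against at most 6.7 elsewhere.

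Gene groups outside the segment moved little between genotypes. Genes of choroid plexus and meninges, tissues attached to the cerebellum, lay higher in Ts1Cje, with 10 of 12 positive and a median of 0.26 (adjusted p = 9.28e-05 by camera, adjusted p = 0.776 with an estimated correlation). Ptgds, a prostaglandin D synthase of the meninges, had 0.32 ± 0.12 and the growth factor Igf2 0.29 ± 0.11. Genes of astrocytes and Bergmann glia lay lower, with 14 of 16 negative and a median of -0.085 (adjusted p = 0.017, and 0.791 with an estimated correlation). Apoe had -0.042 ± 0.11 and Aldoc -0.23 ± 0.16. Interferon response genes lay higher, with 9 of 11 positive and a median of 0.11 (adjusted p = 0.0322, and 0.811 with an estimated correlation), where B2m, the light chain of MHC class I, had 0.39 ± 0.15 and H2-D1 0.12 ± 0.13. The interferon call ended without either P15 pool (-0.003) or either P30 pool (0.096), and the astrocyte call without either P0 pool (-0.061) or either P30 pool (-0.038). No call of camera for genotype held with an estimated correlation, and fry called the trisomic list and the endothelium list (0.15, adjusted p = 0.00775 by fry and 0.0802 by camera), in which Vwf alone passed over the list alone.

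The other lists were not called for genotype over all pools. Their medians were 0.079 for cell division (adjusted p = 0.0802), -0.059 for oxidative phosphorylation (0.0662), -0.15 for cholesterol synthesis (0.213), -0.011 for myelin (0.273) and 0.16 for GABA interneurons (0.304). They were -0.096 for synapse (0.441), -0.053 for ionotropic receptors (0.441), -0.019 for Purkinje cells (0.649), -0.021 for granule cell progenitors (0.649) and 0.049 for microglia (0.673). For the rest they were 0.028 for brainstem (0.673), 0.016 for mature granule cells (0.948), 0.005 for stress genes (0.948), -0.009 for immature neurons (0.993) and 0.002 for ribosomal proteins (0.993). Bright members such as Pvalb of Purkinje cells (-0.019 ± 0.10), Cbln1 of granule cells (0.016 ± 0.11), Gad1 of interneurons (0.11 ± 0.10), Mbp of myelin (-0.098 ± 0.10) and Snap25 of synapses (-0.12 ± 0.11) had differences of at most about 1 SE. Some passed only when a pool was left out. These were microglia without either P0 pool (0.25), mature granule cells (0.13), myelin (-0.13), cholesterol synthesis (-0.23) and oxidative phosphorylation (-0.098) without either P15 pool, and brainstem without either P30 pool (-0.19). The lists of chromosome 16 genes in 2 copies, mature granule cells, granule cell progenitors, immature neurons, ribosomal proteins, stress genes and brainstem had a median, mean and test that did not share a sign. Of the blood list, 2 of 8 genes on the array were bright enough, with a mean difference of -0.91, and of the sex-linked list 1 of 4 (Eif2s3y, -0.22 ± 0.19). Both were too short to test.

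Within single stages the genes with the largest differences were mostly different ones at each stage. At P0, Ts1Cje was higher for Thrsp (1.59), Car8, a Purkinje cell protein (1.13), the transcription factor Zic2 (1.01), Fut9 (0.98) and Sh3gl3 (0.93). It was lower for the synaptic vesicle protein Vamp1 (-1.85), the myelin protein Mag (-1.37), angiotensinogen Agt (-1.35), transthyretin Ttr (-1.33) and Syt11 (-1.30). At P15, it was higher for the homeobox gene Shox2 (1.93), Scx (1.84), the peptide somatostatin Sst (1.56), glutamine synthetase Glul (1.42) and Isoc1 (1.36). It was lower for Astn1 (-2.03), Hbb-b2 (-1.40), Hba-a1 (-1.36), Tradd (-1.06) and Zbtb46 (-1.04). At P30, it was higher for the transcription factor Zbtb16 (2.18), the cochaperone Fkbp5 (1.34), Ifnar1 (0.98), the metallothionein Mt2 (0.95) and Itih3 (0.87). It was lower for Hbb-b2 (-1.38), Sst (-1.24), Prcc (-1.18), Fabp7, a lipid-binding protein of radial and Bergmann glia (-1.10), and Ngef (-1.07). Each stage compares 1 pool with 1 pool, so these differences have no replicate check.

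At P0, 264 probe sets were at least 1.5-fold higher and 288 lower in Ts1Cje without overlap between hybridisations. At P15 the counts were 239 and 145, and at P30 170 and 159. Hybridisations of the same pool differed by that fold for 971 and 748 probe sets at P0 (euploid and Ts1Cje), 844 and 748 at P15, and 640 and 671 at P30. Those counts set a single array against a single array, while the genotype counts compare means of 2 arrays and require no overlap. Averaging and the overlap rule both lower a count, so the hybridisation counts are no direct background for the genotype counts. At any fold, 44.3%, 39.5% and 39.4% of probe sets did not overlap, where chance gives 33.3% if the 4 hybridisations vary independently. Outside the trisomic list, the genotype differences of P0 and P15 had r = -0.244 across probe sets, those of P0 and P30 0.115 and those of P15 and P30 -0.042, and genes are not independent replicates. Only 20.6% of other probe sets had the same direction in all 3 stages, where chance gives 25%.

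By list, synapse genes (-0.24, percentile 0.14), astrocyte genes (-0.23, percentile 0.11) and microglia genes (-0.34, percentile 0.4) lay low among random lists in Ts1Cje at P0, and the choroid plexus and meninges list high (0.38, percentile 100). Members of that list went apart at P0: Ttr (-1.33) and Folr1 (-1.10) of the choroid plexus were lower, and Col1a1 (0.88), Ptgds (0.47) and Igf2 (0.45) higher. At P15, the lists of Purkinje cells (-0.32, percentile 0.03), mature granule cells (-0.34, percentile 0.04) and stress genes (-0.19, percentile 0.26) lay low, and those of microglia (0.42, percentile 99.95), interferon response (0.34, percentile 99.9) and choroid plexus and meninges (0.31, percentile 99.94) high. The Ts1Cje P15 pool also had Xist, the RNA of the inactive X chromosome of females, at 105.6 and 77.6 on its arrays, against 1.4 to 6.7 on the other 10 arrays. It had the lowest signals of the Y-linked Kdm5d (0.6 and 1.9), while Eif2s3y (45.3 and 27.5) and Uty (11.5 and 16.1) were not clearly lower there. At P30, the lists of cholesterol synthesis (-0.48, percentile 0), oxidative phosphorylation (-0.12, percentile 0.01) and astrocytes (-0.16, percentile 0.31) lay low.

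A further model asked whether the genotype difference changed steadily with postnatal day. Limma called 0 of 7453 probe sets, 193 had an unadjusted p under 0.05 (2.59%; 373 by chance; 228 without the trend), and every adjusted p was 1. The smallest p belonged to Igfbp3, an IGF-binding protein, whose difference moved from -0.60 at P0 over 0.47 at P15 to 2.32 at P30 (change of 2.92 ± 0.50, adjusted p = 1, with 0.27 in another probe set). Positive changes followed for the MHC gene H2-K2 (1.74 ± 0.38), Cyp2c39 (2.02 ± 0.46), Ttr (1.73 ± 0.41) and the clock-linked factor Tef (1.61 ± 0.40). Negative ones were those of Clic4 (-1.57 ± 0.34; -0.008 and -0.93 in other probe sets), the DNA repair gene Fancc (-1.84 ± 0.42), Msmo1, an enzyme of cholesterol synthesis (-1.55 ± 0.38), Fabp7 (-1.30 ± 0.34) and Cep250 (-2.33 ± 0.61). With the second hybridisation of each pool alone, 9 probe sets were called, among them Igfbp3, Fancc and H2-K2. This model had the highest share of false calls in simulated data.

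Both genotypes were then used together to follow the development of the cerebellum. Between P0 and P15, most measured genes of myelin, of Purkinje cells and of mature granule cells rose by large factors. Most genes of immature neurons and ribosomal proteins fell, as did 10 of 24 genes of cell division. The calls of these lists by camera were lost with an estimated correlation. In simulated genotype comparisons that setting called a list shifted 1.5-fold in 0 of 20 repeats, and no list shift between stages was simulated. Its loss therefore cannot decide on these lists. Mobp and Mog, proteins of the myelin sheath, and Gabra6, a GABA-A receptor subunit of mature granule cells, went from near background to bright signals. Nnat, an imprinted gene of developing neurons, and St8sia2, which adds polysialic acid to NCAM, were among the largest falls. Limma called 2088 probe sets, 1014 higher at P15 and 1074 lower, for 839 and 857 genes, and 883 of the calls were at least 2-fold.

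The 10 largest rises were Mobp (7.91 ± 0.15, adjusted p = 4.41e-08), Gabra6 (7.90 ± 0.21), the potassium channel Kcna1 (5.77 ± 0.18), Mog (5.57 ± 0.21), Ppp1r17, a phosphatase inhibitor of Purkinje cells (5.49 ± 0.15), Mag (5.07 ± 0.36), Mbp (4.96 ± 0.13), Mybpc3 (4.79 ± 0.19), the actin-severing protein Gsn (4.45 ± 0.21) and Septin4 (4.23 ± 0.14). The P0 signals of Mobp, Gabra6, Mog and Ppp1r17 lay around or below the pseudocount, so the size and order of these rises depend on it. The same holds for falls that ended near background, such as Cdh13 and Gata3. Other probe sets gave 5.81 to 6.43 for Mobp, 6.78 for Gabra6, 3.90 for Ppp1r17 and 2.40 for Septin4, and a further one of Mbp did not follow, with -0.17. The 10 largest falls were Nnat (-3.99 ± 0.23, adjusted p = 1.54e-05), Shox2 (-3.74 ± 0.40), Magel2 (-3.33 ± 0.33), Cdh13 (-3.19 ± 0.29), the serotonin transporter Slc6a4 (-3.17 ± 0.38; -0.64 in another probe set), Tac1, the precursor of substance P (-3.13 ± 0.34), Gata3 (-3.09 ± 0.26), St8sia2 (-2.97 ± 0.16), Rac3 (-2.95 ± 0.29) and Meis2 (-2.94 ± 0.45). Shox2 is also among the genes that differed most between genotypes at P15. Among markers of brain regions next to the cerebellum, euploid signals fell from P0 to P15 for Resp18 (564 to 87), Hap1 (661 to 154) and Tal1 (70.9 to 5.1). Signals rose for Calb2 (284 to 1090), Penk (625 to 762), Cck (114 to 144) and Htr1b (23 to 30.3). A different share of adjoining tissue at P0 was not tested and cannot be told apart from development here.

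Of the myelin list, 11 of 13 genes rose, with a median of 3.68 (adjusted p = 1.9e-09, and 0.323 with an estimated correlation), including Cldn11 (3.97 ± 0.15). Purkinje cell genes rose in 9 of 11 cases (median 2.40, adjusted p = 1.15e-08, and 0.323 with an estimated correlation), among them Calb1 (3.69 ± 0.17), Pvalb (2.83 ± 0.13) and the glutamate transporter Slc1a6 (2.40 ± 0.14). Mature granule cell genes rose in 9 of 11 (median 1.76, adjusted p = 1.25e-08, and 0.323 with an estimated correlation), with Gabrd at 3.92 ± 0.21, the NMDA receptor subunit Grin2c at 3.40 ± 0.27 and Cbln1 at 2.31 ± 0.13. Astrocyte genes rose in 12 of 16 (median 0.88, adjusted p = 1.29e-07, and 0.323 with an estimated correlation), led by S100b (3.91 ± 0.17), Hopx (2.67 ± 0.14), Aqp4 (2.19 ± 0.15) and Gfap (2.67 ± 0.21). In the synapse list 8 of 16 rose and 1 fell (median 0.49, adjusted p = 0.000183, and 0.36 with an estimated correlation): Snap25 (1.94 ± 0.13) and Syt2 (1.78 ± 0.17) rose, and Stx1a, the syntaxin of the release machinery, fell by 1.78 ± 0.29. Oxidative phosphorylation genes rose in 8 of 48 cases, by a median of 0.22 over the list (adjusted p = 0.00106, and 0.455 with an estimated correlation), for example Cycs (0.81 ± 0.18). Without the euploid or the Ts1Cje P30 pool this call ended (adjusted p = 0.0941 and 0.0932), and ionotropic receptors (0.30) passed.

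Immature neuron genes fell in 15 of 18 cases and rose in 1 (median -1.32, adjusted p = 3.88e-09, and 0.323 with an estimated correlation), with Elavl2 at -2.14 ± 0.18, Gap43, a growth cone protein, at -1.66 ± 0.17 and Crmp1 at -1.43 ± 0.14. Ribosomal protein genes fell in 19 of 25 (median -0.59, adjusted p = 1.04e-07, and 0.36 with an estimated correlation), among them Rpl10a (-1.17 ± 0.14) and Rplp0 (-0.97 ± 0.12). Cell division genes fell in 10 of 24 (median -0.52, adjusted p = 0.000171, and 0.323 with an estimated correlation), with Rrm2, a subunit of ribonucleotide reductase, at -1.13 ± 0.25, Hmgb2 at -1.32 ± 0.30 and the DNA ligase Lig1 at -0.91 ± 0.20. Adjusted over the list alone, 16 immature neuron, 20 ribosomal protein and 15 cell division genes fell. Fry called all 9 of these lists too, with adjusted p from 0.00409 to 0.0488, and also the lists of ionotropic receptors (0.017), GABA interneurons (0.0481) and endothelium (0.0488).

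Lists without a call by camera for this step still held changed genes. Fos (1.82 ± 0.16) and Ier2 (1.23 ± 0.23) of the immediate early genes rose, while the chaperones Hspa1a (-1.14 ± 0.19) and Dnaja1 (-0.73 ± 0.13) fell. Among granule progenitor genes Pax6 (1.49 ± 0.27) and Ptch1 (0.91 ± 0.19; 0.051 in another probe set) rose and Sfrp1 (-0.77 ± 0.23) fell. Of the interneuron genes Nos1 (1.75 ± 0.24), Gad1 (0.49 ± 0.13) and Kit (0.56 ± 0.16) rose and Tfap2b fell (-1.70 ± 0.28). In the brainstem list Nefh, the heavy neurofilament, rose (1.51 ± 0.19) and the homeobox genes Hoxa2 (-1.10 ± 0.25) and Hoxa5 (-2.02 ± 0.62) fell; for Hoxa5 the fall was -3.72 in euploid and -0.32 in Ts1Cje. The trisomic, granule progenitor, interneuron and microglia lists had a median, mean and test that did not share a sign. Without the Ts1Cje P15 pool, in which Xist was present, 1853 probe sets were called.

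**Figure D4:**
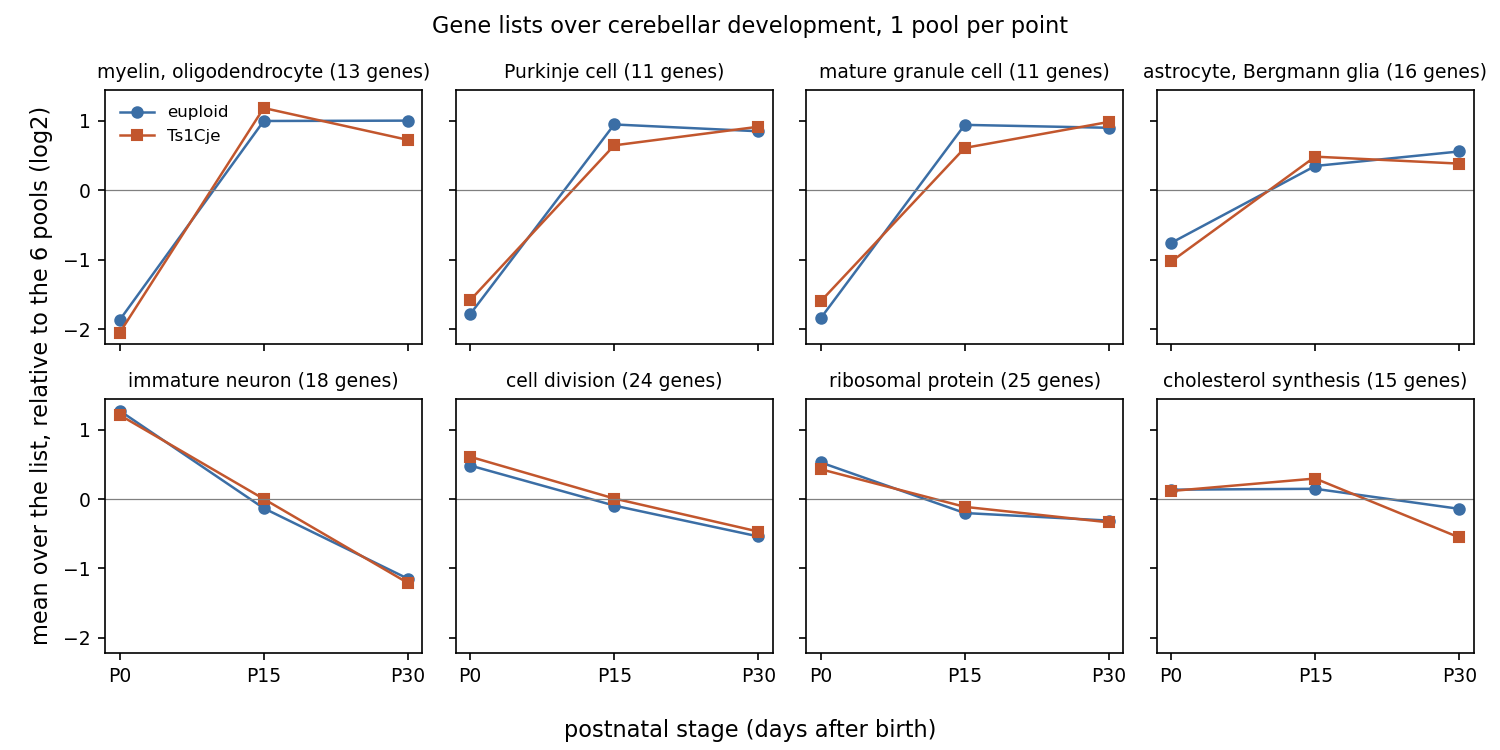
Mean log2 level of 8 gene lists at P0, P15 and P30, relative to the mean of the 6 pools; each point is 1 pool (blue euploid, red Ts1Cje). The myelin, Purkinje, granule and astrocyte lists stand higher at P15 and P30 than at P0, and the immature neuron list goes from 1.27 to -1.15 in euploid and from 1.21 to -1.21 in Ts1Cje.

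Between P15 and P30 the changes were fewer and falls outnumbered rises. Dcx, a microtubule protein of migrating neurons, Sox11, a transcription factor of young neurons, and Mki67, a marker of dividing cells, fell steeply. Ttr, Kl and Folr1, which are made in the choroid plexus, rose, as did the MHC class I genes H2-K1 and H2-D1. Limma called 353 probe sets, 120 higher at P30 and 233 lower, for 99 and 199 genes, 181 of them at least 2-fold.

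The 10 largest rises were Ttr (2.51 ± 0.35, adjusted p = 0.0088), Klk6, a protease of oligodendrocytes (2.40 ± 0.43), Patj (2.23 ± 0.21), Kl (2.15 ± 0.25), Folr1 (2.00 ± 0.37), Nbl1 (1.86 ± 0.19), S100a8 (1.74 ± 0.27), the epoxide hydrolase Ephx1 (1.73 ± 0.23), Mapk12 (1.598 ± 0.16) and Pfn1 (1.59 ± 0.23). The 10 largest falls were Dcx (-4.15 ± 0.19, adjusted p = 3.36e-05), Sox11 (-3.97 ± 0.16), Igfbpl1 (-3.59 ± 0.26), Insm1, a factor of neuronal progenitors (-3.14 ± 0.27), Basp1 (-2.91 ± 0.18; -1.31 in another probe set), Mycl (-2.83 ± 0.17), Marcksl1 (-2.41 ± 0.15), Stx1a (-2.40 ± 0.29), Ly6d (-2.36 ± 0.26) and Mki67 (-2.30 ± 0.28), for which another probe set gave 0.15. The P30 signals of Mki67, Igfbpl1, Insm1 and Stx1a lay near or below the pseudocount, so the size and order of these falls depend on it.

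Immature neuron genes fell in 8 of 18 cases (median -0.53, adjusted p = 1.65e-11, and 0.36 with an estimated correlation), including Nhlh1 (-1.91 ± 0.29). Cholesterol synthesis genes fell in 3 of 15 (median -0.45, adjusted p = 5.39e-05, and 0.662 with an estimated correlation): Lss (-1.19 ± 0.22), Sqle (-1.04 ± 0.20) and Hmgcs1 (-1.23 ± 0.27). For Hmgcs1 the fall was -0.55 in euploid and -1.91 in Ts1Cje. Cell division genes fell in 4 of 24 (median -0.39, adjusted p = 0.00136, and 0.586 with an estimated correlation), among them Cdk1 (-1.57 ± 0.24), Cks2 (-1.597 ± 0.29) and Ezh2 (-0.97 ± 0.18). Of the ribosomal protein genes 1 of 25 fell, Rplp0 (-0.57 ± 0.12; list median -0.19, adjusted p = 0.0124, and 0.663 with an estimated correlation). Interferon response genes rose in 4 of 11 (median 0.68, adjusted p = 0.000291, and 0.662 with an estimated correlation), namely H2-K1 (1.16 ± 0.15; 0.84 and 0.23 in other probe sets), H2-D1 (0.82 ± 0.15), the ubiquitin-like Isg15 (1.12 ± 0.22) and Ifitm3 (1.15 ± 0.24). The synapse list had a median of 0.23 with 1 rise, Snap25 (0.63 ± 0.13), and 1 fall, Stx1a (adjusted p = 0.0332, and 0.663 with an estimated correlation). The synapse call ended without the euploid P15 (0.17), euploid P30 (0.39) or Ts1Cje P30 pool (0.15). The ribosomal call ended without the euploid P30 (-0.18), Ts1Cje P15 (-0.097) or Ts1Cje P30 pool (-0.15). Lists that passed only with a pool left out were Purkinje cells (0.40), mature granule cells (0.32), interneurons (0.36), stress genes (0.22) and myelin (-0.46) without the euploid P15 pool. Others were myelin without the euploid P30 pool (-0.41), microglia without the Ts1Cje P15 pool (0.40), and granule progenitors (-0.51) and choroid plexus (0.30) without the Ts1Cje P30 pool. Fry called the immature neuron and cell division lists (adjusted p = 0.0175 each), and the endothelium list had a positive median and mean with a negative test.

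Single members of other lists also changed in this step. In the choroid plexus and meninges list Ptgds (1.47 ± 0.14), Kl and Ttr rose while the collagen Col1a1 fell (-1.54 ± 0.25; -0.73 in another probe set). Fabp7 fell (-2.28 ± 0.26) and S100b (0.83 ± 0.17) and Ntsr2 (0.93 ± 0.19) rose among astrocyte genes. Ugt8a (-1.37 ± 0.24) and Pdgfra, a receptor of oligodendrocyte progenitors (-0.83 ± 0.15; 0.037 in another probe set), fell in the myelin list, and Mycn fell among granule progenitor genes (-1.40 ± 0.22). The count depended on single pools: it was 141 without the Ts1Cje P30 pool, 234 without the euploid P30 pool, 508 without the Ts1Cje P15 pool in which Xist was present, and 536 from the 4 pools of these stages alone. With the first hybridisations alone it was 746 and with the second alone 98.

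Across the whole month from P0 to P30, most measured genes of Purkinje cells, mature granule cells, myelin, astrocytes and synapses rose, and most of immature neurons, cell division and ribosomal proteins fell. The calls of these lists by camera were lost with an estimated correlation. Limma called 2904 probe sets, 1446 higher at P30 and 1458 lower, for 1184 and 1176 genes, with 1319 at least 2-fold. Gabra6 (8.13 ± 0.21), Mobp (7.96 ± 0.15, adjusted p = 4.2e-08), Ppp1r17 (6.32 ± 0.15), Kcna1 (5.98 ± 0.18), Mog (4.86 ± 0.21), Septin4 (4.83 ± 0.14), Gabrd (4.80 ± 0.21), S100b (4.75 ± 0.17), Mag (4.65 ± 0.36) and Mbp (4.55 ± 0.13, with 0.27 in another probe set) rose most. Dcx (-5.84 ± 0.19, adjusted p = 2.85e-07), Sox11 (-5.23 ± 0.16), D430019H16Rik (-4.59 ± 0.26), Nnat (-4.27 ± 0.23), Rac3 (-4.25 ± 0.29), Dpysl3, a protein of growing axons (-4.24 ± 0.39), Stx1a (-4.18 ± 0.29), Basp1 (-4.13 ± 0.18), Igfbpl1 (-4.00 ± 0.26; -1.95 in another probe set) and the actin-binding Dbn1 (-3.96 ± 0.21) fell most. Signals of Gabra6, Mobp, Ppp1r17, Mog and Gabrd at P0, and of Igfbpl1 and Dbn1 at P30, lay near background, so these sizes depend on the pseudocount.

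By list over the month, immature neuron genes fell in 16 of 18 cases (median -1.97, adjusted p = 4.09e-12, and 0.342 with an estimated correlation), and ribosomal protein genes in 19 of 25 (median -0.80, adjusted p = 2.87e-07), with Rps19 at -2.21 ± 0.21. Cell division genes fell in 17 of 24 (median -0.89, adjusted p = 1.07e-05) and cholesterol synthesis genes in 8 of 15 (median -0.49, adjusted p = 0.0239), such as Nsdhl (-0.81 ± 0.16). Purkinje cell genes rose in 9 of 11 (median 2.84), mature granule cell genes in 10 of 11 (median 1.80) and myelin genes in 11 of 13 with 1 fall (median 2.49), each with adjusted p = 8.57e-07. Astrocyte genes rose in 13 of 16 and fell in 2 (median 1.52, adjusted p = 1.22e-05), synapse genes rose in 13 of 16 and fell in 1 (median 0.80, adjusted p = 7.88e-05), and interferon response genes rose in 6 of 11 (median 0.75, adjusted p = 0.0238), with H2-K1 at 1.58 ± 0.15 (1.31 and 0.62 in other probe sets). With an estimated correlation the adjusted p of these lists was 0.342 to 0.514, so no list call of camera held in any stage comparison. That setting also called the shifted list in 0 of 20 simulated genotype comparisons, so it cannot decide on these calls. Fry called 8 of these 10 lists, all but interferon response (0.0685) and cholesterol synthesis (0.144), and also GABA interneurons, ionotropic receptors (0.0125 each), endothelium (0.0168) and stress genes (0.0419). Oxidative phosphorylation stood at 0.16 (adjusted p = 0.0504), where Sdha, a subunit of complex II, rose (1.29 ± 0.20). Outside the called lists, Fos (2.44 ± 0.16), Dusp1 (1.85 ± 0.23), the microglial protease Ctss (1.26 ± 0.19), the glucose transporter Slc2a1 (1.19 ± 0.16) and Tiam1 (2.79 ± 0.20; 0.43 in another probe set) rose. Mycn (-1.98 ± 0.22), the collagen Col3a1 (-1.83 ± 0.25) and Rcan1 (-1.61 ± 0.18) fell. The list of chromosome 16 genes in 2 copies had a positive median with a negative mean and test. Without the Ts1Cje P30 pool 1830 probe sets were called. The interferon call ended without the euploid P30 (0.60), Ts1Cje P0 (0.45) or Ts1Cje P30 pool (0.56), and the cholesterol call without the Ts1Cje P0 (-0.55) or Ts1Cje P30 pool (-0.33). Ionotropic receptors passed without the euploid (0.93) or Ts1Cje P30 pool (0.565), and oxidative phosphorylation without either P15 pool.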

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

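The Xist test below was chosen after the result was seen; the tests of neighbouring brain tissue and of tissue maturity were written down before their own values were looked at.

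A signal in a gene outside the comparisons stood out first: Xist, which lay below the signal filter, had a mean of 91.6 in the Ts1Cje P15 pool, against pool means of 2.6 to 5.9 in the others. Other results stood out because the genotype difference of a gene list had opposite signs at different stages, with all 4 pairings of hybridisations on one side at one stage and all 4 on the other side at another. Each stage has 1 pool per genotype, so the difference between stages was not tested for any of these lists. Purkinje cell genes had median differences of 0.091 at P0, -0.323 at P15 and 0.052 at P30. Stress and immediate early genes had 0.138, -0.191 and -0.022, and microglia genes -0.342, 0.416 and 0.013. Interferon response genes had -0.191, 0.341 and 0.214. Astrocyte and Bergmann glia genes had -0.235, 0.09 and -0.161, myelin genes -0.099, 0.037 and -0.117, and oxidative phosphorylation genes -0.079, 0.009 and -0.117. Cholesterol synthesis genes had 0.051, 0.121 and -0.477, where the P30 value was the lowest of these lists. For 7 of these 8 lists, all but cholesterol synthesis, the P15 difference had the opposite sign to the P0 difference. The lists were selected for opposite signs between stages, so this count is partly fixed by that rule and is no separate result.

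The pattern weighed was the Ts1Cje P15 pool, with Xist present and markers of Purkinje and mature granule cells lower than in the euploid pool. Markers of brain regions next to the cerebellum had a median difference of 0.305 at P15 (percentile 100 of 10000 matched lists, 14 of 16 higher), with signals in euploid and Ts1Cje of 87 and 212 for Resp18, 68.2 and 149 for Nefm, 83.6 and 146 for Nefl and 3.6 and 16.5 for Prph (the 4 largest, picked after their values were seen), so neighbouring tissue is a candidate explanation. The evidence for it is mixed. Outside this list, Shox2 (1.933), Meis2 (1.844), Slc6a4 (1.531) and Tac1 (0.883) were also higher at P15. Their signals were 1.45 to 10.25 in euploid and 13.5 to 44.1 in Ts1Cje. They are among the largest falls from P0 to P15 named above, of which only St8sia2 (-0.249) was lower. Such genes cannot tell neighbouring from less mature tissue. Other markers such as Gata2 (0.023), Gal (0.031), Calb2 (0.042) and Penk (0.081) hardly differed, and Cck (-0.17) and Htr1b (-0.364) were lower. The marker list was extreme the other way at P0 (-0.204, percentile 0.66, 3 higher) and P30 (-0.173, percentile 1.06, 5 higher). The brainstem and hindbrain list fixed earlier did not stand out at P15 (0.183, percentile 89.97, 4 of 7 higher). Most of the markers (not Prph and Tal1 after P0) have signal in the other pools. Less mature tissue cannot be told apart from other causes: the slope of the P15 difference on the change from P0 to P30 was -0.037, with -0.083 to 0.009 over the 4 pairings of hybridisations. The lower Xist signal of the pool was at least 11.6 times the highest elsewhere, where Xist lay near background. Its presence may thus reflect female cerebella. Of the Y-linked genes, Kdm5d, dim in all pools, had its lowest signals in this pool (0.6 and 1.9), while Eif2s3y and Uty were not clearly lower. Sex was not used here, and a biological effect of genotype at P15 stays open and untested beside these.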

How the results depend on the processing

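All alternatives below were set down before the data were examined. The median of the trisomic list stayed positive and past camera's threshold under every scaling, pseudocount, filter, left-out pool and left-out stage (0.347 without a signal filter to 0.505 with quantile normalization, adjusted p of 3.31e-38 to 4.48e-18 at the preset correlation). With an estimated correlation the same 0.488 had an adjusted p of 0.115, the highest of its alternatives. In simulated data that setting never called such a list, but simulated genes varied independently of each other. The simulation therefore cannot tell which correlation setting is right for these pools. Under some settings the median by stage moved by more than its SD between hybridisations (0.056 at P0 and 0.008 at P15). At P0 it moved from 0.483 to 0.406 with the 40th percentile pseudocount and 0.422 without a filter, both within the 0.389 to 0.468 of either hybridisation alone. At P15 it moved from 0.427 to 0.469 with quantile normalization and to 0.456 and 0.35 with the 5th and 40th percentile pseudocounts. It was 0.347 there without a filter and 0.454 with the 60th percentile filter (0.411 to 0.423 with either hybridisation alone). A larger pseudocount and dimmer genes lower a log ratio by construction, and signal over background limits what dim genes can show.

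Calls for P15 against P0 stayed within 1499 to 2669, and those for P30 against P0 ranged from 1830 without the Ts1Cje P30 pool to 3299 without stage P15 among settings that left out samples. Calls for P30 against P15 fell to 199 without a filter and 183 without the trend, were 536 from only the 4 pools compared, and ranged from 98 to 746 when samples were left out; the Ts1Cje P30 pool (141 without it) and the euploid P30 pool (234) lowered them most among pools. Of the 353 calls, 49.9% were kept without a filter, 50.7% without the trend, 34.6% without the Ts1Cje P30 pool and 26.1% with the second hybridisations alone. For genotype, leaving out either pool of a stage takes that stage out of the comparison, so both ways are the same check. Genotype calls ranged from 0 to 6 with samples left out (6 without either P30 pool, 1 without either P0 pool, 4 without stage P30), and day calls from 0 to 9, the latter with the second hybridisations alone. The cause was not tested.

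Deviations of hybridisations under the same number went together between genotypes within each stage (r of 0.275 at P0, 0.354 at P15 and 0.14 at P30) and among the P0 and P15 pools (0.15 to 0.354), but not between these and the P30 pools (-0.124 to 0.071). The numbers thus did not pair all the pools; each pool mean holds both numbers, while pairings of hybridisations within a stage are not independent. With the hybridisation number as a block, the pool as a random block (consensus correlation 0.153) and all 12 arrays, genotype calls went to 6 (Hbb-b2, Son, Tmem50b, Vwf, Eomes and Atp5o), P30 against P15 to 898, and day stayed at 0.

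Gene list calls, 4 for genotype, 9 for P15 against P0, 6 for P30 against P15 and 10 for P30 against P0, all went to 0 with an estimated correlation, and fry gave 2 for genotype and 2 for P30 against P15. With samples left out they ranged from 2 (without the first hybridisations) to 7 (without either P15 pool) for genotype and from 5 to 10 (without the euploid P15 pool) for P30 against P15. Among results past the threshold under at least 1 of the settings compared, direction turned for 3: the genotype difference of the interferon response list (-0.003 without either P15 pool or that stage, to 0.26 without a P0 pool), that of the brainstem list (-0.188 without either P30 pool or that stage, to 0.116) and the change of Igfbp4 from P0 to P30 (0.037 with the first hybridisations alone, -1.316 with the second). Within a stage, 1.2-fold gave 2205, 1807 and 1643 differences at P0, P15 and P30, and 2-fold gave 100, 73 and 51. Over all alternatives, list results stayed on their side of the threshold 1643 times, became stronger 51 and weaker 71 times, and named genes 6146, 43 and 245 times. Those that stayed include 306 changes of sign between values past the threshold under neither setting; the others kept their direction. Lists within a stage moved by more than their spread 123 times and did not 468 times. The cause was not tested.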

Other observations

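The tests of a globin strain variant, of saturated globin probe sets, of less blood, and of the brighter trisomic genes were chosen after the results were seen; the others were written down before.

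Cdca7l, with a difference of 0.93, was the last of 179 measured genes of chromosome 12, the partner of chromosome 16 in the translocation; the 5 genes before it, looked up after its value was seen, had 0.049 (Nudt14), 0.28 (Crip2), -0.057 (Ighd), 0.046 (Ighm) and 0.14 (Ighv5-12).

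The erythroid genes Hbb-b2, Hba-a1 and Alas2, picked by their small p, had negative differences at each stage, but none passed correction. Slc4a1, just under the signal filter, had signals in euploid and Ts1Cje of 19 and 7.8 at P0, 27.1 and 22.2 at P15, and 18.8 and 19.8 at P30. A strain variant at the beta-globin locus, as the whole cause, would leave Hba-a1, on another chromosome, unmoved, and it had -0.83. Saturated or cross-hybridising globin probe sets would leave Alas2, a dim gene that is not a globin, unmoved, and it had a difference of -1. Hba-a1 and Alas2 were picked by these same differences, so the values cannot decide on either of these explanations. Less blood in the Ts1Cje tissue would lower Hba-a1 and Alas2 alike, and their gap within a stage was at most 0.31, under 3 times its error between hybridisations at each stage (0.67, 0.758 and 1.14). Hbb-b2 was not part of that test: at P30 it lay a further -0.72 from Hba-a1, 3.04 times the error with the genes taken apart and 2.16 times the error of gaps within an array. These errors are between hybridisations of single pools and leave the gaps undecided, so less blood cannot be told apart from fewer or different red cells in these animals, and no biological explanation was tested.

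The trisomic list had a median of 0.49, below the 0.585 that 1.5-fold would give. Compression by the pseudocount is argued against by a median that hardly moved, at 0.489 (bootstrap SE 0.043), with the 5th percentile pseudocount. For compression of dim probe sets, the 9 genes with a mean signal of 200 or more had 0.504 (SE 0.03), still below 0.585. Some dim members were low, such as Chaf1b (0.087), Sh3bgr (0.188) and Ifnar2 (0.228), while Setd4 (0.906) and C2cd2 (0.575) were not. The SE is over genes that share the same 6 pools and leaves out the error between pools. Compression of dim probe sets therefore stays undecided. Cross-hybridisation and background within MAS5 signals could not be examined from summarised values, and regulation of single genes toward the level of 2 copies was not tested.

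Another segment with a changed copy number was searched for in 5482 windows of 10 neighbouring measured genes. Outside the trisomic list the largest window median in size was -0.191 (Ptprd to Dennd4c on chromosome 4), within the 0.256 that marked the 95th percentile of maxima in shuffled gene orders, while the window from Ifnar1 to Setd4 in the segment had 0.532. A median over 10 genes cannot show a segment that holds only a few measured genes. The chromosome 12 segment near the translocation, listed as having lost a copy, had 0 tested genes and was not examined.

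The pools make too few splits for a share under 0.05. Of the 9 other splits, 6 divide only 1 stage by genotype and so give the genotype difference of that stage, which is no chance value; 3 divide every stage. For genotype calls, 10 of 10 splits gave as many as the real 0 (highest other 0). For the trisomic median 1 of 10 did (0.488; highest other 0.483, the P0 difference), and the 3 that divide every stage gave 0.168, 0.193 and 0.112. For genotype list calls, 8 of 10 splits gave as many as the real 4 (highest other 9), where the 3 gave 3, 9 and 2, and for day calls 4 of 4 gave as many as the real 0 (highest other 24, from the split that exchanged the P30 pools).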
